A study of Mus musculus with 40 samples.

How the data were processed

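Total RNA from the cerebellum of male C57BL6 mice was sequenced in 40 libraries, and the columns of all 40 were used. Per the labels, RNA was extracted with trizol and chloroform, depleted of ribosomal RNA and sequenced on a DNBseq instrument. The deposited table holds a signal per gene and library, which is an estimated read count normalised by the authors. Per the submitters' processing notes the tools were Bowtie2, Salmon and DESeq2 and the genome build was mm9, without versions or order. The values are not whole numbers, and the median ratio of each library to the geometric mean over genes is equal in all libraries, as median-of-ratios scaling gives. A step of 1 read was estimated at 0.883 to 1.15, and 11% to 60.4% of low values lay within 0.02 of a whole number of steps, so raw counts could not be recovered. Sums per library are therefore not depths, and no counting interval or floor was computed.

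Gene symbols and positions came from the GENCODE M21 annotation on GRCm38, matched by gene ID. Of 54331 IDs, 53444 matched with their version and 54097 without it. The build of the annotation differs from the mm9 of the notes, so positions belong to the annotated genes and not to the authors' alignments. Genes with a value of at least 10 in at least 4 libraries were tested, which left 21367 genes, of which 16143 were protein-coding.

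Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with empirical Bayes moderation with an intensity trend and robust variances. All 8 groups stood in 1 fit with 1 mean per group and no covariate, since the labels name no batch and no pairing. The 4 WT SD libraries are numbered 39 to 42 without a break, and the labels do not say what the numbers mean. A handling order that followed these numbers could not be told apart from the WT SD group. Calls are genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 18 planned comparisons were KD against SD over all genotypes and within each, each genotype against WT and DKO against CSB on each diet, differences in diet response from WT, and the interaction of the CSB and INDY genotypes on each diet. The other 4 comparisons (both averages over diets and DKO against INDY on each diet) were added after the first results were seen. Group values are mean ± SD, and errors of log2 differences are standard errors of the fit. Folds are 2 to the size of the log2 difference.

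Gene lists numbered 41, 25 of pathways and 16 of cell types, and were written before the data were examined, as were the planned comparisons, the filter, the test and most alternatives. A liver list of 20 genes was added later, left out of the counts of lists and given with unadjusted p; 2 of its genes reached 10 in every WT SD library. Of the 18 forebrain genes 2 also stood in another list, and of the 22 tested choroid plexus genes 22 reached 10 in every WT SD library. Lists were tested with camera with a preset correlation of 0.01, repeated with an estimated correlation, and with fry, adjusted over the lists of a comparison. Counts adjusted over the list alone used Benjamini-Hochberg within the list.

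The genes named in the text were fixed by a rule: Slc13a5 and Ercc6 in every comparison, the 12 called genes per direction with the smallest p in 5 main comparisons and the 5 per direction in the others. The 12 per direction were also used for the CSB and DKO average, which was added after the first results were seen. Genes had to have a mean of at least 20 and a symbol that is not a clone or model name, and all calls were named where there were 5 or fewer. The rule also asked for 3 members of every called list. This part was followed only for the lists described, because 283 pairs of list and comparison were called. Further genes, the 6 calls of DKO against CSB on KD, the library tests, and the forebrain limit of 6.5 were chosen after their values were seen.

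Alternatives planned in advance were pseudocounts of 0.5 and 5, no filter other than leaving out genes at 0 throughout, rescaling by the median ratio over the tested genes (factors of 1.002 to 1.005), fits of only the groups compared, 1 surrogate variable with the groups protected, and leaving out each library in turn. The surrogate variable was computed with an own implementation of the iteratively reweighted algorithm with 5 iterations. Leaving out the 12 libraries with forebrain levels above 6.5, and using the forebrain and liver levels as covariates, were chosen after seeing the data. Each count was also compared over up to 100 splits of the same libraries, the real one included. Similar gene sequences were found by aligning transcripts with minimap2 2.31-r1302. Single libraries far from their group were sought with Dixon's ratio in 208 groups of values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

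The fit was tested on simulated data with known changes. For CSB against WT on SD it called 21 of 67 genes changed 1.5-fold, 52 of 67 changed 2-fold and 60 of 66 changed 4-fold, with 9 unchanged genes called. For KD against SD in WT these numbers were 28 of 67, 50 of 67 and 59 of 66, with 10 unchanged genes. For KD against SD over all genotypes they were 53 of 67, 62 of 67 and 64 of 66, with 10 unchanged genes. For CSB and DKO against WT and INDY they were 55 of 67, 62 of 67 and 65 of 66, with 8 unchanged genes. The simulated libraries hold no tissue mixture, so they say nothing of recovery where other tissue varies.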

Results

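The series measured RNA from the cerebellum of male C57BL6 mice of 4 genotypes, labelled WT, INDY, CSB and DKO, on a standard diet (SD) or a ketogenic diet (KD). INDY is the name of Slc13a5, a sodium-coupled citrate transporter of the plasma membrane. CSB is the protein encoded by Ercc6, a DNA-dependent ATPase of transcription-coupled nucleotide excision repair. The 40 libraries formed 8 groups: 4 WT SD, 4 WT KD, 6 INDY SD, 6 INDY KD, 6 CSB SD, 5 CSB KD, 4 DKO SD and 5 DKO KD. Values were normalised estimated read counts per gene, and their sums ran from 23736702 in WT SD 42 to 32247186 in CSB KD 13. These sums are normalised, so the sequencing depth of each library is unknown. Genes with a value above 0 numbered 25948 to 27406 per library. Mitochondrial genes held 5.97% to 14.2% of the total, and the non-coding RNA Rn7s1 held 5.33% to 15.6%. The Pearson correlation of log2 values between 2 libraries lay between 0.905 and 0.983. The labels do not say whether libraries came from separate animals, so the limma p-values of genes below measure spread between libraries. Fisher's exact p-values count genes as units. Camera p-values with the preset correlation set the genes of a list against the other genes under a fixed correlation.

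Genes typical of other tissues varied among the dissected cerebella. The mean log2 level of a forebrain list was 5.31 ± 0.22 (SD, n = 4) in WT SD and 5.43 ± 0.18 (n = 6) in CSB SD. It was 7.08 ± 1.19 (n = 4) in WT KD and 7.24 ± 1.90 (n = 4) in DKO SD, with 9.41 in DKO SD 1 and 8.25 in DKO SD 35. Of the 18 forebrain genes, 11 also reached 10 in every WT SD library. In 12 libraries the forebrain level exceeded 6.5, a limit chosen after the values were seen, and none of these was WT SD or CSB SD. Leaving out these 12 leaves 1 WT KD library, so in that setting the WT KD value is that of a single library and its spread is taken from the other groups. A choroid plexus list stood at 8.08 ± 0.66 in WT SD and 6.22 ± 1.66 in WT KD. A liver list, added after liver transcripts were noticed, stood at 1.95 ± 0.32 in WT SD, 5.03 ± 2.62 in CSB SD and 4.62 ± 2.52 (n = 6) in INDY SD.

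**Figure D1:**
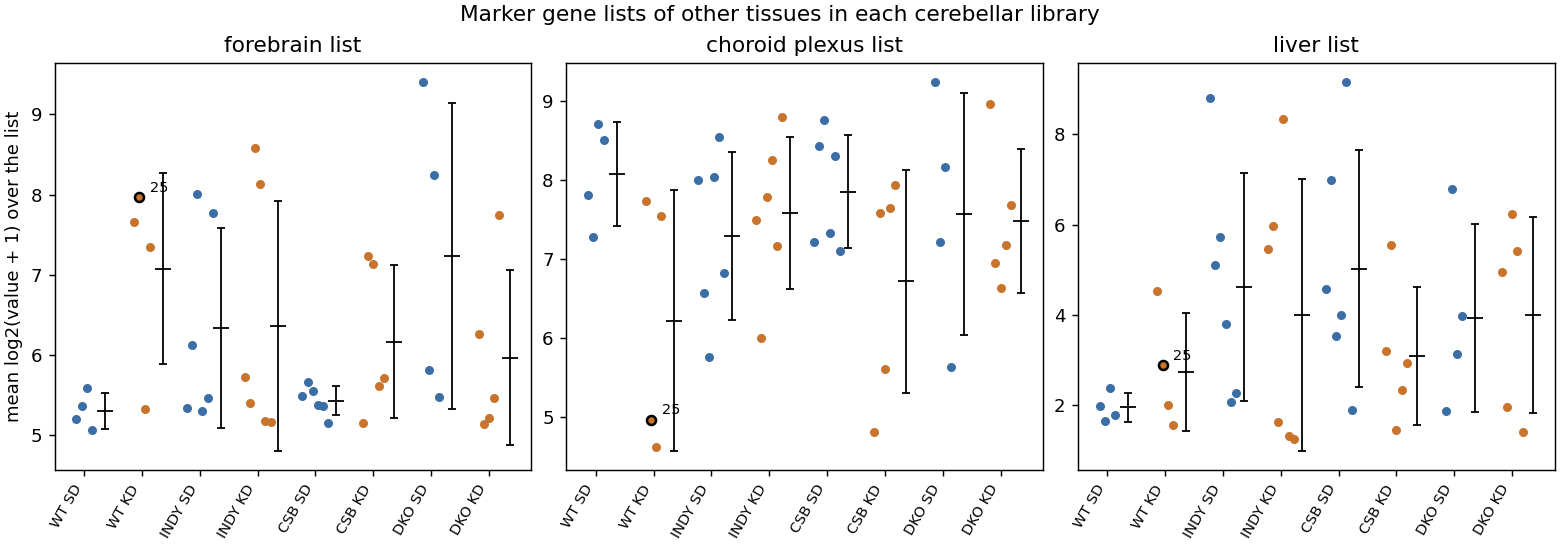
Mean log2 level (value + 1) of the forebrain, choroid plexus and liver lists in each library by group, with points for libraries and bars for mean ± SD; blue is SD and orange is KD. Forebrain levels of the 4 WT SD and 6 CSB SD libraries stay between 5.07 and 5.66, while DKO SD reaches 9.41.

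Slc13a5 (ENSMUSG00000020805.14; GRCm38 chromosome 11, 72241989 to 72267222) read 82.1 to 161 in the 19 WT and CSB libraries. It was listed at 0 in 19 of the 21 INDY and DKO libraries, and the other values were 0.824 in INDY KD 15 and 0.934 in DKO KD 47. Averaged over diets, the adjusted p of this difference was 7.91e-34. Ercc6 (ENSMUSG00000054051.7; chromosome 14, 32513521 to 32580990) stayed present in all libraries. It read 605 ± 98.3 (SD, n = 20) in CSB and DKO and 887 ± 112 (n = 20) in WT and INDY, a log2 difference of -0.55 (SE 0.07, adjusted p = 3.27e-06). On SD the difference was -0.64 in CSB (SE 0.14, adjusted p = 0.0474) and -0.64 in DKO (SE 0.15, adjusted p = 0.0334). These 2 calls were close to the limit: 12 of 18 alternatives ended the first and 8 of 16 ended the second. On KD Ercc6 differed by -0.44 in CSB (SE 0.15, adjusted p = 0.585) and -0.32 in DKO (SE 0.15, adjusted p = 0.776), and between DKO and INDY by -0.56 on SD (adjusted p = 0.2) and -0.56 on KD (adjusted p = 0.0933), and none of these passed. In the other comparisons it ran from -0.22 to 0.32 and did not pass.

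A library labelled WT KD 25 differed from the other WT libraries. Its Ercc6 value was 633, below the 718 to 1070 of the 19 other WT and INDY libraries. Ercc6 read 382.5 to 876.2 in CSB and DKO, and the highest of these, DKO KD 23, lay inside the WT and INDY range. Gm6768 (chromosome 12, 119260978 to 119262855), annotated as a processed pseudogene, was listed at 0 in those 19 libraries. It read 1041 in WT KD 25 and 929 to 1245 in the 20 CSB and DKO libraries. Ncoa4 (chromosome 14, 32159865 to 32179855), the cargo receptor for ferritin in autophagy, read 2362 in WT KD 25, 3071 to 4350 in the 19 others and 2284 to 2935 in CSB and DKO. Gm6768 matches Ncoa4 in 1876 of 1878 bases, which makes the value of either gene alone uncertain. The library kept its label throughout, and the counts of comparisons that include WT KD are also given without it.

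**Figure D2:**
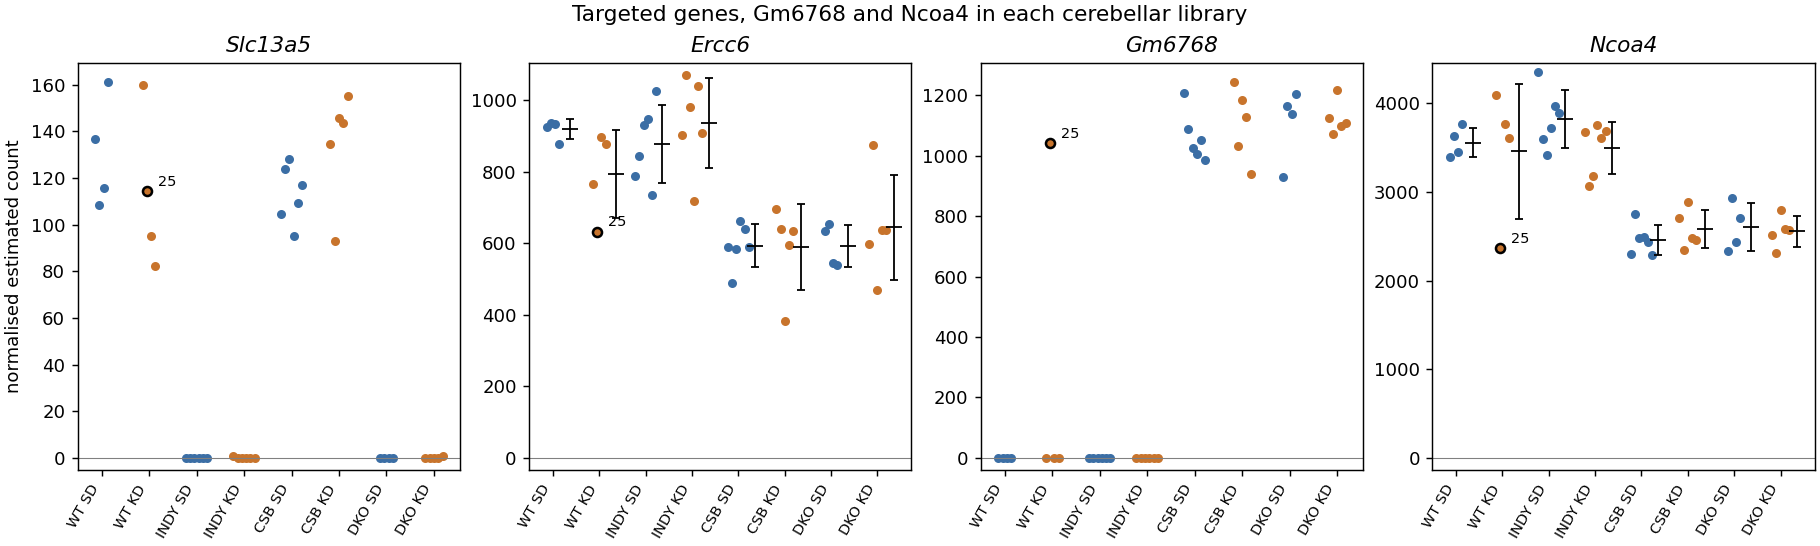
Normalised estimated counts of Slc13a5, Ercc6, Gm6768 and Ncoa4 in each library by group (blue SD, orange KD), with mean ± SD bars for Ercc6 and Ncoa4 and a ring around WT KD 25. The ringed library reads 1041 for Gm6768, where the 19 other WT and INDY libraries are listed at 0.

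CSB was compared with WT on SD to see how the CSB genotype altered the cerebellar transcriptome on the standard diet. Microglial genes were higher in the 6 CSB than in the 4 WT libraries. Cst7, an inhibitor of lysosomal cathepsins, was 6.04-fold higher (log2 2.59, SE 0.43), from 10.1 ± 3.24 to 70.9 ± 39.5. Itgax, the integrin CD11c, was 5.31-fold higher (SE 0.40 in log2), and Gpnmb, a lysosomal glycoprotein of phagocytes, 4.10-fold (SE 0.37). Cd68, a lysosomal membrane protein of macrophages, rose from 80.2 ± 3.59 to 216 ± 49.1, a 2.61-fold difference (SE 0.21, adjusted p = 0.00116). Mpeg1, a perforin-like protein of phagocytes, was 2.55-fold higher and Tyrobp, the signalling adaptor of Trem2, 2.52-fold. Trem2 itself, a lipid receptor of microglia, was 2.13-fold higher. The complement genes C1qa, C1qb and the C3a receptor C3ar1 were 2.06-, 2.05- and 2.20-fold higher. The urokinase gene Plau, the leukocyte integrin Itgb2 and the surface glycoprotein Cd52 were 2.58-, 2.49- and 2.73-fold higher.

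The list of complement and activated microglia genes had 33 tested members with a median log2 difference of 1.08, and 29 of them lay above 0. Of these, 13 were called over all genes tested, all higher, and 26 were called when adjusted over the list alone. Camera gave adjusted p = 2.45e-38 with the preset correlation, and adjusted p = 0.00798 with an estimated correlation. Of 738 pairs of planned lists and comparisons, 283 were called with the preset correlation, 1 with the estimated one and 13 by fry. The MHC class II genes of the list did not pass: Cd74 differed by -0.03 (SE 0.39), H2-Aa by -0.09, H2-Ab1 by -0.28 and H2-Eb1 by 0.06. The 22 general microglia markers had a median of 0.67, with 2 called and 15 called when adjusted over the list alone (adjusted p = 2.35e-19 preset, adjusted p = 0.218 with an estimated correlation). The mean log2 level of these markers was lowest in WT SD (7.87), with 8.50 in CSB SD but also 8.37 in WT KD, 8.22 in INDY SD and 8.14 in INDY KD, so much of this difference was shared by groups without the CSB genotype. The interferon and antigen presentation list had a median of 0.31, with 0 of 42 members called and 4 when adjusted over the list alone (adjusted p = 1.94e-07 preset, adjusted p = 0.522 with an estimated correlation). Gfap, the astrocyte filament protein, differed by 1.16 (SE 0.35, adjusted p = 0.363) and Timp1, a metalloproteinase inhibitor, by 1.25 (SE 0.35, adjusted p = 0.277), and neither passed. In the same libraries the 20 tested liver genes had a median difference of 3.40, with 0 called and an unadjusted p = 0.0849 with an estimated correlation. Mup20, a major urinary protein made by liver, reached 466 ± 941 in CSB SD against 1.61 ± 2.04 in WT SD.

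In total 29 of 21367 genes were called between CSB and WT on SD, 26 higher and 3 lower, and 1683 had an unadjusted p under 0.05. Gm6768 was among the higher genes, while Ncoa4 fell by 0.54 on the log2 scale (SE 0.099, adjusted p = 0.00826). The count was 10 without WT SD 41, 18 without WT SD 39, 50 without CSB SD 30, and 11 with the forebrain and liver levels as covariates. All 29 genes differed in the same direction between DKO and INDY on SD, which are separate libraries, and 27 did so with an unadjusted p under 0.05. Over all genes that share was 4.41%. This is not a matched baseline, because both comparisons came from 1 fit and used the same variance estimate for each gene. Between DKO and INDY on KD 29 shared the direction and 24 had such a p (6.68% of all genes). Between CSB and WT on KD, with WT KD 25 included, 24 and 11 did (4.91%). Chromosome 14 carries Ercc6, so 24 of the 29 genes, all on other chromosomes, were also counted alone. Of these, 24 shared the direction between DKO and INDY on SD and 22 had such a p. On KD these numbers were 24 and 19 between DKO and INDY, and 19 and 7 between CSB and WT.

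**Figure D3:**
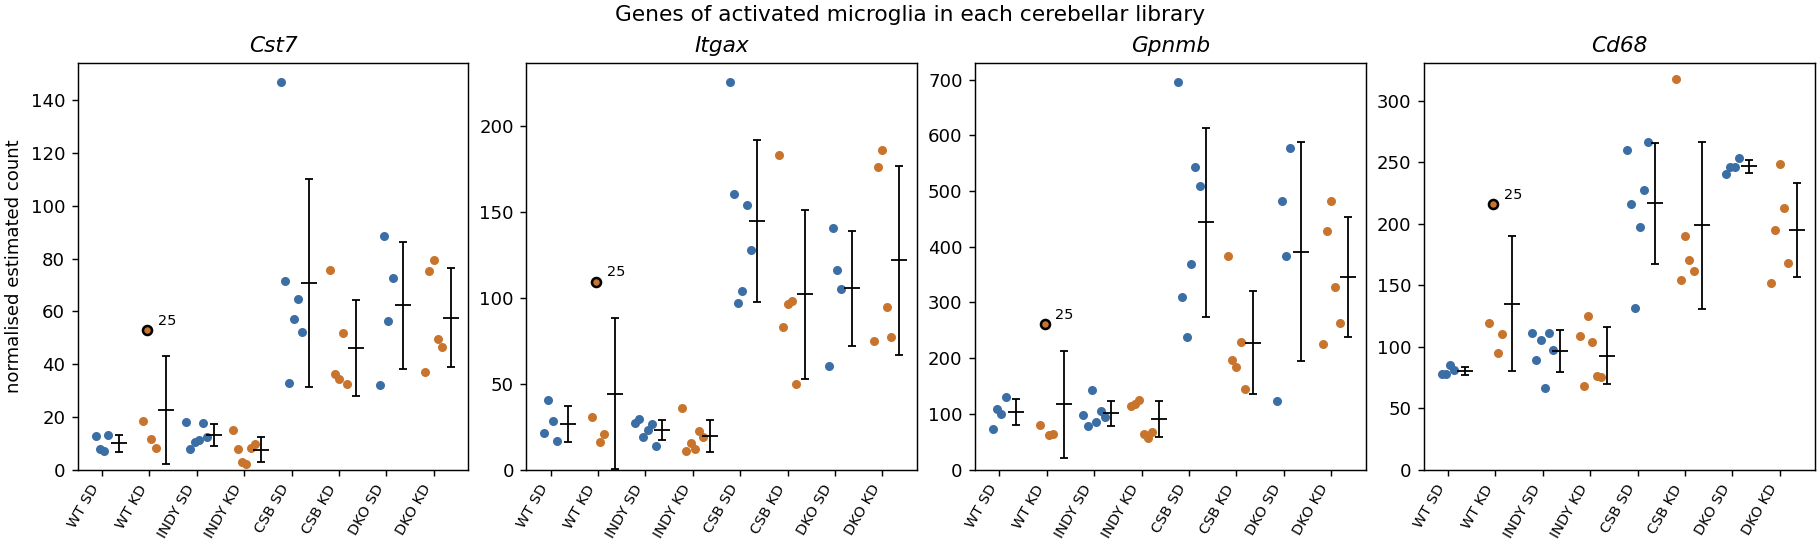
Normalised estimated counts of Cst7, Itgax, Gpnmb and Cd68 in each library by group (points for libraries, bars for mean ± SD, blue SD, orange KD). Itgax lies between 49.76 and 225.5 in the 20 CSB and DKO libraries, between 10.93 and 40.8 in 19 WT and INDY libraries, and at 109.5 in WT KD 25.

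Averaged over both diets, the 20 CSB and DKO libraries were compared with the 20 WT and INDY libraries, a comparison added after the first results were seen. Itgax was 4.44-fold higher (log2 2.15, SE 0.20), Cst7 4.70-fold (SE 0.21), Gpnmb 3.30-fold (SE 0.18), Cd68 2.15-fold (SE 0.11) and Clec7a, the beta-glucan receptor dectin-1, 3.40-fold (SE 0.18). Tyrobp, Mpeg1, Trem2, C1qa and C3ar1 were 1.90-, 1.87-, 1.85-, 1.68- and 1.67-fold higher. Of the 33 complement and activated microglia genes 25 were called higher, and adjusted over the list alone 26 were higher and 1 lower. Their median was 0.69, with adjusted p = 3.47e-47 preset and adjusted p = 0.00211 with an estimated correlation. In the interferon and antigen presentation list 6 of 42 genes were called and 25 when adjusted over the list alone (median 0.31, adjusted p = 2.22e-18 preset, adjusted p = 0.29 with an estimated correlation). Called members included B2m, the light chain of MHC class I (1.39-fold), Psmb8, a subunit of the immunoproteasome (1.39-fold), and Lgals3bp, a secreted glycoprotein (1.47-fold). Among reactive astrocyte genes 4 of 21 were called and 6 higher when adjusted over the list alone, with Serpina3n at 2.01-fold and Timp1 at 1.79-fold (adjusted p = 3.32e-05 preset, adjusted p = 0.372 with an estimated correlation). The call of Serpina3n ended in 25 of 47 alternatives. The lysosomal protease gene Ctss was 1.56-fold higher and the apolipoprotein gene Apoe rose by 0.34 on the log2 scale (SE 0.059).

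This averaged comparison called 170 genes, 121 higher and 49 lower. The count was 1378 without INDY KD 22, 959 without DKO KD 23 and 276 without INDY SD 33. Without the 12 libraries with forebrain levels above 6.5 it was 727, of which 139 were among the 170. Without WT KD 25 it was 182, of which 154 were shared.

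The called genes were unevenly placed. On chromosome 14, which carries Ercc6, 21 of the 170 were found against 805 of the 21367 tested (one-sided Fisher's exact p = 1.81e-06, and p = 1.93e-05 without Ercc6 and Ncoa4), and 19 of these lay within 15 Mb of Ercc6. Galnt15, a glycosyltransferase gene at 32028989 to 32062197, fell by 1.85 (SE 0.21) and Ldb3, a Z-disc protein gene, fell by 1.07 (SE 0.14). Mettl6, a tRNA methyltransferase, and Syt15, a synaptotagmin, fell by 0.28 and 0.55. Sh3bp5 (31359880 to 31436078), a regulator of Rab11, was 1.44-fold higher and Plau (20836660 to 20843385) 2.07-fold. Ncoa4 fell by 0.49 (SE 0.049), but the sum of Ncoa4 and Gm6768 differed by 0 (SE 0.037). Among called genes on other chromosomes Cd200r3, a receptor of myeloid cells, fell by 0.69, Itga10, a collagen-binding integrin, by 0.65, Olfr1277, an olfactory receptor, by 0.66, and Polr3e, an RNA polymerase III subunit, by 0.23. Gucd1 and Ankrd10 fell by 0.24 and 0.21, and the call of Ankrd10 ended in 28 of 47 alternatives.

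**Figure D4:**
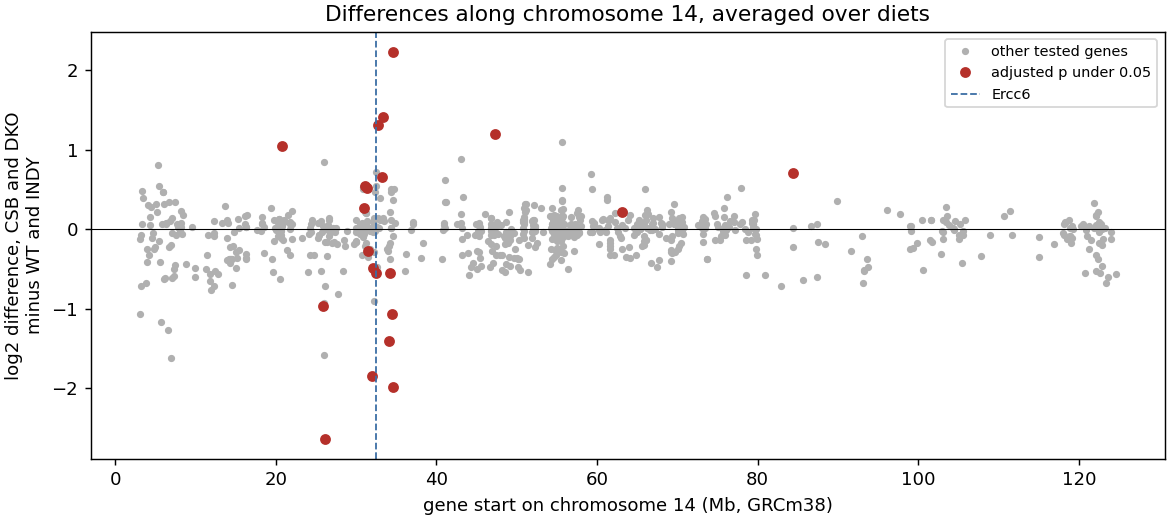
Log2 difference between CSB and DKO and WT and INDY, averaged over diets, of each tested gene of chromosome 14 against its start in Mb (GRCm38), with called genes in red and Ercc6 as a dashed line. Of the 21 called genes, 19 lie within 15 Mb of Ercc6.

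The CSB genotype was also tested as DKO against INDY, within each diet. These libraries are separate from those of CSB against WT, but they are part of the average above and give it no independent support. On SD, Cd68 was 2.57-fold, Itgax 4.35-fold, Clec7a 3.72-fold, Fcgr2b, the inhibitory Fc gamma receptor, 1.82-fold and Plau 2.33-fold higher, while Galnt15 fell by 2.32, Ldb3 by 1.4 and Ncoa4 by 0.56. Plau, Galnt15, Ldb3 and Ncoa4 lie on chromosome 14 within 15 Mb of Ercc6. Chromosome 14 held 4 of 13 calls on SD and 5 of 21 on KD, against 3.77% of tested genes (one-sided Fisher's exact p = 0.00109 and 0.000922). Sequence linked to Ercc6 was not separated from the genotype for these calls. On KD, Cst7 was 7.62-fold (SE 0.40 in log2), Itgax 6.02-fold, Clec7a 4.83-fold and Gpnmb 3.82-fold higher. Catspere1, annotated as an unprocessed pseudogene, was 15.3-fold higher (adjusted p = 0.000345), but it read 7.52 in DKO KD 3 and did not follow the CSB genotype, with 9.126 to 12.97 in CSB KD. Nvl (chromosome 1, 181087138 to 181144204), a ribosome biogenesis ATPase, fell by 0.56, Cyyr1 by 0.73 and Ncoa4 by 0.45. The complement and activated microglia list had a median of 0.82 on SD (5 called, 23 when adjusted over the list alone, adjusted p = 9.96e-35 preset, adjusted p = 0.0142 with an estimated correlation). On KD its median was 0.75 (8 called, 25 when adjusted over the list alone, adjusted p = 9.3e-34 preset, adjusted p = 0.0167 with an estimated correlation). On SD 13 genes were called, 10 higher and 3 lower, and the count was 2 without DKO SD 36, 3 without DKO SD 35, 4 without DKO SD 34 or INDY SD 32, 6 without INDY SD 11, and 7 without the libraries with high forebrain levels. On KD 21 genes were called, 18 higher and 3 lower, with 8 without DKO KD 24, 37 with 1 surrogate variable, 32 without WT KD 25, which is in the same fit, and 1 in a fit of these groups only. The call of Plau on SD ended in 9 of 18 alternatives, and on KD those of Cyyr1 and Ncoa4 ended in 12 and 10 of 19.

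DKO, in which both Slc13a5 and Ercc6 were low, was compared with WT on SD. Cd68 rose from 80.2 ± 3.59 to 246 ± 5.57 (3.05-fold, SE 0.23 in log2, adjusted p = 0.000283). Cst7 was 5.55-fold, Tyrobp 2.62-fold, Mpeg1 2.48-fold, C1qa 2.28-fold, C1qb 2.21-fold, C3ar1 2.18-fold and Plau 2.64-fold higher. Adgre1, the macrophage receptor F4/80, Nckap1l, a WAVE complex subunit of blood cells, and Fcgr2b were 2.21-, 2.08- and 1.93-fold higher. Among genes that fell were Galnt15 (-2.80), Il17re, an interleukin 17 receptor subunit (-1.85), Stard5, a sterol-binding protein (-1), Plod2, a lysyl hydroxylase (-0.87), and Ltbp3, a binding protein of latent TGF-beta (-0.82). Spag5, a mitotic spindle protein, Slc4a7, a bicarbonate transporter, Afap1, an actin-binding protein, Malsu1, a mitochondrial ribosome factor, Pde7a, a cyclic AMP phosphodiesterase, and Ncoa4 fell by 0.79, 0.58, 0.55, 0.53, 0.47 and 0.46.

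By list, 18 of 33 complement and activated microglia genes were called (23 when adjusted over the list alone, median 1.09, adjusted p = 1.9e-13 preset, adjusted p = 0.452 with an estimated correlation). Of 22 general microglia markers 14 were called (19 when adjusted over the list alone, adjusted p = 2.67e-13 preset, adjusted p = 0.452 with an estimated correlation); their level was 8.69 in DKO SD and 7.87 in WT SD, below the 8.14 to 8.37 of WT KD, INDY SD and INDY KD. Of 79 cytosolic ribosomal protein genes 20 were called (72 when adjusted over the list alone, median 0.43, adjusted p = 2.13e-21 preset, adjusted p = 0.568 with an estimated correlation), including Rplp1 at 1.66-fold and Rps2 at 1.63-fold. WT SD had the lowest level of the 8 groups for this list (11.07 against 11.24 to 11.53) and for mitochondrially encoded mRNAs (14 against 14.28 to 14.54), so part of these differences was not particular to DKO. Of 13 mitochondrially encoded mRNAs 4 were called (10 when adjusted over the list alone, median 0.46, adjusted p = 1.77e-06 preset, adjusted p = 0.452 with an estimated correlation). The complex I gene mt-Nd3 was 2.77-fold higher, a value made uncertain by the copy Gm28438, identical to it in 342 of 342 aligned bases. The antioxidant enzyme gene Gpx1 was 1.55-fold higher. The forebrain list had a median of 1.74, with 2 of 18 called (7 when adjusted over the list alone, adjusted p = 0.000174 preset, adjusted p = 0.568 with an estimated correlation). Its neuronal calmodulin-binding gene Nrgn was 10.2-fold and the dopamine receptor gene Drd2 3.25-fold higher. The Purkinje cell list had a median of -0.91 with 0 called and 11 lower when adjusted over the list alone (adjusted p = 0.000143 preset, adjusted p = 0.568 with an estimated correlation). Its glutamate transporter gene Slc1a6 differed by -1.35 (SE 0.48) and did not pass, and over 16 alternatives it ran from -1.84 to -0.14. The mean log2 level of the Purkinje cell list was 8.65 and 10.16 in DKO SD 1 and 35, which had high forebrain levels. It was 11.06 and 11.72 in DKO SD 34 and 36, near the 11.08 to 11.83 of WT SD. The lower level thus lay mainly in the DKO SD libraries with high forebrain levels, and a change of Purkinje cells was not tested.

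DKO against WT on SD called 1265 genes, 662 higher and 603 lower. The count depended on single libraries and settings: it was 12 without WT SD 41, 23 without WT SD 39, 65 without WT SD 42, 398 without WT SD 40, 44 without DKO SD 35 and 101 without DKO SD 1. It was 69 without the low-value filter, 694 in a fit of these groups only, 5 with 1 surrogate variable and 7 with the forebrain and liver levels as covariates. Of 16 alternatives, 11 ended the call of Nrgn, 9 those of Drd2, Rplp1, Rps2 and Stard5, and 8 those of Gpx1, Malsu1, Ncoa4 and Pde7a.

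DKO against CSB on SD asked what the INDY genotype added to the CSB genotype. Slc13a5 was the 1 gene called, with 2908 genes at an unadjusted p under 0.05. The forebrain list had a median of 2.01 with 0 of 18 called and 6 when adjusted over the list alone (adjusted p = 6.35e-07 preset, adjusted p = 0.783 with an estimated correlation). Nrgn differed by 2.79 (SE 0.94), Emx2, a transcription factor of the cortex, by 3.05 (SE 1.0) and the synaptic scaffold gene Homer1 by 0.86 (SE 0.27), and none of these passed. The count was 5 without the libraries with high forebrain levels, 3 with the forebrain and liver levels as covariates, 3 without the low-value filter and 2 in a fit of these groups only.

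INDY was compared with WT on SD to see the effect of the citrate transporter genotype alone. Slc13a5 was the 1 gene called, and 3063 genes had an unadjusted p under 0.05. Genes of energy metabolism had small positive differences, but WT SD had the lowest mean log2 level of the 8 groups for these lists, so the differences were not particular to INDY. The oxidative phosphorylation level was 10.88 in WT SD and 10.96 to 11.21 in the other groups, that of mitochondrially encoded mRNAs 14 and 14.28 to 14.54, and that of glycolysis 11.71 and 11.79 to 11.96. The glycolysis list had a median of 0.22, with 0 of 23 called and 7 when adjusted over the list alone (adjusted p = 2.42e-07 preset, adjusted p = 0.65 with an estimated correlation). Eno1, a glycolytic enolase, differed by 0.36 (SE 0.098) and Aldoa, an aldolase, by 0.38 (SE 0.10), each with adjusted p = 0.319. The oxidative phosphorylation list had a median of 0.23 with 69 of 70 genes above 0, 0 called and 0 when adjusted over the list alone (adjusted p = 7.07e-14 preset, adjusted p = 0.65 with an estimated correlation). Cox6a1, a cytochrome oxidase subunit, differed by 0.34 (SE 0.11), mt-Cytb by 0.39 (SE 0.12) and Mdh2, a malate dehydrogenase, by 0.25 (SE 0.091), and none passed. The 20 liver genes had a median of 2.50 with 0 called (unadjusted p = 0.187 with an estimated correlation), and WT SD also had the lowest forebrain levels. A fit of these groups only, or no low-value filter, gave 2 calls.

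Averaged over diets, the 21 INDY and DKO libraries against the 19 WT and CSB libraries gave 3 called genes. These were Slc13a5, Gm28438, which was lower, and mt-Nd3, which was 1.56-fold higher (log2 0.64, SE 0.12, adjusted p = 0.0312). The call of mt-Nd3 ended in 24 of 47 alternatives, with adjusted p up to 0.781. The sum of mt-Nd3 and its copy Gm28438 differed by 0.19 (SE 0.082). The count was 6 without CSB SD 26, 5 without INDY KD 46 or WT KD 28, 5 with a pseudocount of 5, 2 without WT KD 25, and 1 without the libraries with high forebrain levels. The interaction of the CSB and INDY genotypes was tested within each diet: limma called 0 genes on SD (701 at an unadjusted p under 0.05) and 0 on KD (981). On KD the count was 3 without CSB KD 13, 2 without DKO KD 3, 1 without INDY KD 22 or WT KD 28, 1 with a pseudocount of 5 or no low-value filter, and 24 without the libraries with high forebrain levels, which left 1 WT KD library. It was 0 without WT KD 25.

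The ketogenic diet was compared with the standard diet over all 4 genotypes. None of the genes of ketone body use passed the test. Oxct1, the enzyme that activates ketone bodies, differed by -0.04 (SE 0.047) and Bdh1, the beta-hydroxybutyrate dehydrogenase, by -0.05 (SE 0.058). The 12 genes of ketone body use and transport had a median of 0 with 0 called and 0 when adjusted over the list alone (adjusted p = 0.994 preset). Pdk4, a starvation-induced kinase of pyruvate dehydrogenase, differed by -0.02 (SE 0.088). Choroid plexus genes had a median of -0.70, with 0 of 22 called and 0 when adjusted over the list alone (adjusted p = 4.29e-13 preset, adjusted p = 0.407 with an estimated correlation). Among them the channel subunit Kcne2 differed by -1.46 (SE 0.63), the folate receptor Folr1 by -1.27 (SE 0.58), Klotho (Kl) by -0.97 (SE 0.42) and the thyroxine carrier Ttr by -1.58 (SE 0.77), and none passed. Erythrocyte genes had a median of -0.56 and a mean of -0.35, with 0 of 9 called and 5 lower when adjusted over the list alone (adjusted p = 7e-07 preset, adjusted p = 0.364 with an estimated correlation). The globin genes Hbb-bs and Hba-a1 differed by -0.62 and -0.58 (SE 0.20 each). The oxidative phosphorylation list had a median of 0.06 with 0 of 70 called and 0 when adjusted over the list alone (adjusted p = 1.06e-09 preset, adjusted p = 0.723 with an estimated correlation). Limma called 0 of 21367 genes, and 676 had an unadjusted p under 0.05. The count was 2 without DKO KD 3, 6 without the libraries with high forebrain levels and 0 without WT KD 25.

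Within WT, limma called 0 genes between KD and SD, with 2868 at an unadjusted p under 0.05. Mitochondrially encoded mRNAs had a median of 0.49 with 0 of 13 called and 8 when adjusted over the list alone (adjusted p = 5.71e-08 preset, adjusted p = 0.522 with an estimated correlation). The mitochondrial genes mt-Cytb and mt-Nd1 differed by 0.49 (SE 0.14) and 0.50 (SE 0.15), Eno1 by 0.37 and Aldoa by 0.38 (SE 0.11 each), and none passed. Choroid plexus genes had a median of -1.82 with 0 of 22 called, and 1 higher and 11 lower when adjusted over the list alone (adjusted p = 1.25e-09 preset, adjusted p = 0.522 with an estimated correlation). Its member Calml4 differed by -2.70 (SE 0.88), and Fabp7, a fatty acid carrier of radial glia and Bergmann glia, by -0.59 (SE 0.17). WT KD held 3 of the 12 libraries with high forebrain levels and WT SD none. Without WT KD 28 the count was 17, without WT SD 40 or 41 it was 1, without the low-value filter 3, and without the libraries with high forebrain levels, which left 1 WT KD library, 50. It was 0 without WT KD 25.

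Within INDY limma called 0 genes for KD against SD (989 at an unadjusted p under 0.05), and without INDY SD 32 the count was 1. The citrate synthase gene Cs differed by -0.18 (SE 0.072), and the 27 TCA cycle genes had a median of -0.12 with 0 called and 0 when adjusted over the list alone (adjusted p = 4.9e-08 preset, adjusted p = 0.733 with an estimated correlation). Within CSB limma called 0 genes (732 at an unadjusted p under 0.05), and 2 in a fit of these groups only. The clock output gene Dbp differed by 0.44 (SE 0.13), the complement gene C3 by -2 (SE 0.60) and the small heat shock gene Hspb1 by -0.81 (SE 0.24), and none passed. The circadian clock list had a median of 0.21 with 0 of 19 called and 1 when adjusted over the list alone (adjusted p = 1.65e-06 preset, adjusted p = 0.462 with an estimated correlation), and the liver list stood at 5.03 ± 2.62 in CSB SD and 3.09 ± 1.52 (n = 5) in CSB KD (unadjusted p = 0.139 with an estimated correlation).

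Within DKO, Catspere1 (chromosome 1, 177808550 to 177962233), annotated as an unprocessed pseudogene, was the 1 gene called for KD against SD. It was 16.3-fold higher (log2 4.03, SE 0.65, adjusted p = 0.00827). It read 355, 252, 295 and 298 in DKO KD 2, 23, 24 and 47, but 7.52 in DKO KD 3 and 8.41 ± 3.03 (n = 4) in DKO SD. The call ended without DKO KD 2, 23, 24 or 47 or DKO SD 1 or 34, in a fit of these groups only, and without the libraries with high forebrain levels. There were 2 calls without DKO KD 3, without WT KD 25, without the low-value filter or with a pseudocount of 5. Granule cell genes had a median of 0.91 with 0 of 19 called and 0 when adjusted over the list alone (adjusted p = 1.05e-06 preset, adjusted p = 0.895 with an estimated correlation). The granule cell genes Fat2, a protocadherin, and Gabra6, a GABA receptor subunit, differed by 2.28 (SE 0.86) and 2.43 (SE 0.93), the Purkinje cell gene Pcp2 by 2.18 (SE 0.82) and Drd2 by -1.27 (SE 0.38), and none passed. The forebrain level was 7.24 ± 1.90 in DKO SD and 5.97 ± 1.09 in DKO KD, and without the libraries above 6.5 Fat2, Gabra6 and Pcp2 differed by -0.15, -0.24 and -0.16.

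DKO against CSB on KD gave 6 called genes. Catspere1 was 11.9-fold higher (SE 0.61 in log2), and Ifi202b, an interferon-inducible DNA-binding protein, was also higher, both with adjusted p = 0.00996. Ifi202b read 21.6, 27.7, 22.3 and 17.1 in DKO KD 2, 23, 24 and 47 and was listed at 0 in DKO KD 3. In CSB KD it was listed at 0 in 4 of 5 libraries and read 0.913 in CSB KD 18, so the size depends on the pseudocount: the log2 difference was 3.42 with 1 and 1.89 with 5, and over all 18 alternatives it ran from 1.89 to 4.33. Catspere1 and Ifi202b both lie on chromosome 1 (177808550 to 177962233 and 173962568 to 173982744). Both were higher in DKO KD 2, 23, 24 and 47 than in DKO KD 3, so neither followed the DKO label in all libraries. Sequence from another strain near them was not tested. The other calls were Slc13a5 and the gene models Gm28438, Gm7336 and Gm12671. Gm7336 and Gm12671 match Gapdh in 1229 of 1232 and 1002 of 1002 bases, so their values, like that of Gapdh, are uncertain. The count was 1 without DKO KD 2, 23, 24 or 47, 3 without CSB KD 13, 18, 19, 43 or 44, and 3 with a pseudocount of 0.5, without the low-value filter or without the libraries with high forebrain levels.

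On KD, comparisons with WT included the library labelled WT KD 25. That library was singled out by values of Gm6768, Ercc6, Ncoa4 and microglial genes like those of CSB and DKO. Leaving it out therefore enlarges such differences by choice, so the calls of these genes gained without it give no separate support. CSB against WT gave 1 call, Gm6768, with Itgax at 1.49 (SE 0.41), Gpnmb at 1.16 (SE 0.39) and B2m at 0.51 (SE 0.15), none of which passed. Without WT KD 25 there were 10 calls, among them Itgax (2.06, SE 0.38, adjusted p = 0.0195), Ncoa4, Galnt15, Ldb3 and Sh3bp5. The count was 9 without WT KD 28, 18 without the libraries with high forebrain levels, which left 1 WT KD library here and in the comparisons below, 4 without the low-value filter and 0 in a fit of these groups only. DKO against WT gave 2 calls, Slc13a5 and Gm6768, with Gpnmb at 1.78 (SE 0.39), Itgax at 1.75 (SE 0.41) and Clec7a at 1.41 (SE 0.37). Without WT KD 25 there were 24 calls, among them Gpnmb (2.26, SE 0.37), Itgax (2.32, SE 0.38), Cst7 (2.11, SE 0.44) and Clec7a (1.77, SE 0.38). The count was 15 without WT KD 28, 8 without DKO KD 3 or without the low-value filter, 18 without the libraries with high forebrain levels, and 4 with 1 surrogate variable, the 2 covariates or a pseudocount of 5. INDY against WT gave 2 calls, Slc13a5 and Heg1, an endothelial receptor, at 1.60-fold (log2 0.68, SE 0.12, adjusted p = 0.0304). Calml4 differed by 2.21 (SE 0.81) and the growth factor gene Igf2 by 1.39 (SE 0.47), and neither passed. The count was 4 without WT KD 25, with Heg1 no longer called, 4 without WT KD 7, 24 without WT KD 28, 16 without the libraries with high forebrain levels and 5 without the low-value filter. It was 1 without INDY KD 15, 45 or 46 or WT KD 12, with the 2 covariates or in a fit of these groups only, and 9 of 18 alternatives ended the call of Heg1.

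The response to diet was tested for a difference between each genotype and WT. For INDY 3 genes passed: Wdr18, a ribosome biogenesis factor (-0.71, SE 0.13), Zbtb34, a zinc finger protein (1.38, SE 0.25), and Heg1 (0.93, SE 0.17), each with adjusted p = 0.0429. Heg1 read 1098 ± 155 and 755 ± 82.1 in WT SD and KD, and 920 ± 113 and 1211 ± 118 in INDY SD and KD. No call was left without INDY KD 20, 22, 45 or 46, INDY SD 9, 10 or 11, WT KD 7, 25 or 28, or WT SD 40, 41 or 42, with 1 surrogate variable, the 2 covariates, no low-value filter or these groups only. The count was 1 without INDY KD 15, 9 without INDY KD 21, 5 without WT KD 12, 7 without WT SD 39 and 20 without the libraries with high forebrain levels, which left 1 WT KD library. For CSB limma called 0 genes, with 1369 at an unadjusted p under 0.05. For DKO it called 0, with 3988 at an unadjusted p under 0.05, and the count was 617 without DKO SD 36, 4 without DKO KD 47 or WT KD 28, 3 without WT SD 40, 2 without DKO KD 3 and 14 without the libraries with high forebrain levels. Without WT KD 25 the counts for CSB and DKO were 0.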

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

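The tests of WT KD 25, of the CSB and DKO average by chromosome, of the Ncoa4 copy, of the forebrain level, of liver, of chromosome 14 without Ercc6 and Ncoa4 and of other splits were chosen only after the result was seen; those of chromosome 14 for CSB on SD, of chromosome 11, of the choroid plexus and of WT SD were written before.

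In the library labelled WT KD 25, 136 of 182 genes called without it between CSB or DKO and the rest lay nearer the CSB and DKO mean, against 7 to 98 in the 19 other WT and INDY libraries; 22 of these 25 genes on chromosome 14 and 114 of 157 elsewhere did so. A swap with a CSB or DKO library of the series is argued against, because 0 of those 20 libraries had the low Gm6768 value that a partner would need. RNA of a CSB or DKO animal mixed into a WT library is argued against by the 24 genes of chromosome 14 among them other than Ncoa4: on a scale from the mean of the other WT and INDY libraries (0) to that of CSB and DKO (1) their median stood at 0.95, against 0.82 to 1.21 in the CSB and DKO libraries; a small share of WT RNA is not excluded by this. A WT animal with only the segment around Ercc6 stays open, because a segment that itself changed microglial RNA would give the same values. The complement and activated microglia list stood at 7.89, against 6.53 to 7.70 in the other WT and INDY libraries and 7.66 to 8.58 in CSB and DKO. Itgax read 109.5 and Gpnmb 261.2, and both lie on other chromosomes. By a thin margin, these values argue only against a segment without effect on microglial RNA. A wrong genotype label could account for these values but stays open, since the share of 74.7% missed the limit set for it by less than 1 gene, the library was singled out by the same genes, and no biological explanation was tested. A true genotype of DKO is argued against by Slc13a5, at 114.2 in this library and 0 to 0.9344 in the 21 INDY and DKO libraries.

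In the CSB and DKO average, calls were more frequent on chromosome 14 than among tested genes (Fisher's exact p = 1.81e-06, and p = 1.93e-05 without Ercc6 and Ncoa4), which is consistent with sequence from another strain around the Ercc6 allele. In CSB against WT on SD this stays open: the p of 0.0225 counts the targeted gene itself, and it was 0.0867 without Ercc6 and 0.27 without Ercc6 and Ncoa4. For the 149 of the 170 calls on other chromosomes strain sequence was not tested. For Ncoa4 the sum with Gm6768 differed by 0 (SE 0.037), which is consistent with reads of Ncoa4 counted under the copy. Liver RNA is argued against as the whole source of the microglial difference, because the list kept a median of 0.98 of its 1.08 with the liver level as covariate, although Alb read 1410 ± 2448 in CSB SD and 15.1 ± 8.60 in WT SD. Of other brain regions only the forebrain was tested here, and hindbrain tissue was not. Forebrain tissue is argued against as the whole source of the microglial difference, because the forebrain level differed by 0.13 between CSB SD and WT SD, less than the SD of 0.22 in WT SD. The same holds for the CSB and DKO average, where 139 of the 170 calls stayed without the 12 libraries with high forebrain levels; this does not cover the calls that ended. An effect of the CSB genotype on microglial RNA stays open as a hypothesis. Strain sequence elsewhere was not separated from it, and copies of the microglial genes were not searched for.

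Of the 1265 calls of DKO against WT on SD, 15 stayed called with the forebrain level as covariate. Over all 1265 the median difference went from 0.86 to 0.62 and the median standard error from 0.24 to 0.23. Why the calls ended was not tested, and these genes were chosen by their differences in the first fit. Leaving out the libraries with high forebrain levels instead gave 1140 calls, 439 of them shared; the forebrain gene Nrgn read 1992 ± 1923 in DKO SD and 152 ± 105 in WT SD. For the calls that ended with the covariate, forebrain tissue and a genotype effect therefore cannot be told apart, because only 2 DKO SD libraries lay below the forebrain limit. For the 15 that stayed, forebrain tissue as the whole source is argued against. Slc13a5 and Cd68 stayed called in all 16 alternatives. This reading was settled after both counts of calls were seen. The median share of the difference that lay between WT SD and the 6 other groups was 0.51, but WT SD enters both sides of that test, so it decides nothing. Leaving out WT SD 41 alone gave 12 calls, and the cause was not tested.

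Calls on chromosome 11 in INDY against WT on SD could not be judged, with 1 call and a Fisher's exact p of 0.0666. The choroid plexus covariate left 0 calls of 0 for the diet average, so it decides nothing there.

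For several counts, at most 5% of splits of the same libraries gave as many calls, with the real split among those counted. Each count was read alone, without adjustment over the comparisons, so chance is not excluded for the set. Both averages and both comparisons of DKO against INDY were added after the first results were seen. Where the highest other split gave more calls than the real one, a count of that size arose without the labels. For CSB against WT on SD, with 29 calls, 1 of 100 splits gave as many and the highest other gave 1. For DKO against WT on SD, with 1265 calls, 1 of 35 did (highest other 1), and for DKO against INDY on SD, with 13 calls, 1 of 100 (highest other 1). For the CSB and DKO average, with 170 calls, 2 of 100 did, and the highest other gave 535. By the same limit, few splits also gave as many for DKO against CSB on KD (6 calls, 1 of 100, highest other 2) and the INDY and DKO average (3, 1 of 100, 2). So it was for DKO against INDY on KD (21, 3 of 100, 1904) and the diet response of INDY against WT (3, 2 of 100, 10). For INDY against WT on SD (1, 3 of 100, 1) and DKO against CSB on SD (1, 4 of 100, 942) the 1 call was Slc13a5. The genotype labels fix that call, so these 2 counts decide nothing beyond this gene. Slc13a5 was also called in DKO against CSB on KD and in the INDY and DKO average. Some of these counts are weak evidence, because runs without 1 library moved them by more than 1.5 times: 17 of 20 runs for the diet response of INDY, 9 of 10 for DKO against CSB on KD (down to 1), 6 of 8 for DKO against WT on SD (down to 12), 5 of 10 for DKO against INDY on SD (down to 2), 3 of 10 for CSB against WT on SD (down to 10), 3 of 40 for each average and 1 of 11 for DKO against INDY on KD.

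Chance was not excluded for the counts on KD of CSB against WT (1 call, 18 of 100 splits, highest other 1176), INDY against WT (2, 13 of 100, 1483) and DKO against WT (2, 9 of 100, 7), nor for that of KD against SD in DKO (1, 11 of 100, 186). A count does not judge a single gene: Slc13a5 had limma adjusted p = 1.15e-22 in INDY and 5.54e-22 in DKO against WT on KD. The other comparisons had 0 calls, so all splits gave as many: 100 of 100 for the diet average (highest other 2815), for the diet in INDY (581) and in CSB (0), for the diet response of CSB (5) and DKO (187) against WT, and for the interaction on SD (1) and KD (2593), and 35 of 35 for the diet in WT (3). Splits with 186 to 2815 calls where the real one gave 0 to 170 point to a structure of the samples that the groups do not follow.

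Single libraries stood far from their group in 14 of 208 groups of values tested, where chance flags about 1 in 20. In WT KD these were Gm6768 at 1041 (others at 0), Itgax at 109.5 (others 16.03 to 30.61) and Gpnmb at 261.2 (others 61.55 to 80.88), all in library 25. Slc13a5 read 0.8239 in INDY KD 15 and 0.9344 in DKO KD 47, with the others at 0. In CSB SD 16, Cst7 read 146.9 (others 32.86 to 71.44), the Purkinje cell list 9.94 (others 10.98 to 11.59) and the meningeal fibroblast list 7.13 (others 8.08 to 8.65). The cerebellar inhibitory interneuron list read 8.70 in DKO SD 1 (others 9.65 to 9.79). The unipolar brush cell list read 7.84 in WT SD 40 (others 8.32 to 8.36). The endothelial cell list read 8.67 in WT SD 41 (others 8.78 to 8.80) and 8.97 in INDY SD 10 (others 8.67 to 8.75). In CSB KD 13 the mural cell list read 6.78 (others 7.25 to 7.43) and the complement and activated microglia list 8.26 (others 7.66 to 7.75). The diet response differed between INDY and WT by the interaction test for Wdr18 (-0.71), Zbtb34 (1.38) and Heg1 (0.93).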

How the results depend on the processing

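Leaving out the libraries with high forebrain levels and using the forebrain and liver covariates were chosen only after the result was seen; all other alternatives were planned. The values were normalised, so TMM or size factors, filterByExpr and DESeq2, planned for counts, were not run. For the changes below the cause was not tested, except that leaving out libraries leaves fewer samples. Of 186 gene results, 186 kept direction and side of the threshold with the rescaled values and with a pseudocount of 5, 185 with 0.5, 166 without the low-value filter, 148 with 1 surrogate variable, 145 with the covariates and 145 without the libraries with high forebrain levels; with only the groups compared 117 of 143 did, and 2870 of 3196 over all single libraries left out. The depth behind each value is unknown, which limits low values most.

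List calls went from 283 to 1 with the estimated correlation and 13 with fry. The surrogate variable was positive in each library with a high forebrain level, so it and the forebrain covariate are not independent settings. With 1 surrogate variable, counts became 37 for DKO against INDY on KD, 8 on SD, 4 for DKO against WT on KD, 5 for DKO against WT on SD and 0 for the diet response of INDY. With the covariates they became 11 for CSB against WT on SD, 3 for DKO against CSB on SD, 4 and 7 for DKO against WT on KD and SD, 1 for INDY against WT on KD and 0 for the diet response of INDY. Without the low-value filter they became 4, 5 and 8 for CSB, INDY and DKO against WT on KD, 2 and 69 for INDY and DKO against WT on SD, 3 for DKO against CSB on KD and on SD, 1 for the interaction on KD, 2 for the diet in DKO, 3 in WT and 0 for the diet response of INDY. With only the groups compared they became 0 and 1 for CSB and INDY against WT on KD, 2 and 694 for INDY and DKO against WT on SD, 2 for DKO against CSB on SD, 1 for DKO against INDY on KD, 2 and 0 for the diet in CSB and DKO and 0 for the diet response of INDY. With a pseudocount of 5 they became 1 for the interaction on KD, 4 for DKO against WT on KD, 5 for the INDY and DKO average and 2 for the diet in DKO, and with 0.5, 3 for DKO against CSB on KD. Without the libraries with high forebrain levels, which left 1 WT KD library whose spread came from the other groups, they became 18, 16 and 18 for CSB, INDY and DKO against WT on KD, 727 and 1 for the CSB and DKO and the INDY and DKO averages, 24 for the interaction on KD, 3 and 5 for DKO against CSB on KD and SD, 7 for DKO against INDY on SD, 6, 50 and 0 for the diet on average, in WT and in DKO, and 14 and 20 for the diet response of DKO and INDY.

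Leaving out single libraries of the groups compared gave, on SD, 10 to 50 calls for CSB against WT, 1 to 1 for INDY against WT, 12 to 1826 for DKO against WT, 1 to 1 for DKO against CSB, 2 to 14 for DKO against INDY and 0 to 0 for the interaction. On KD it gave 1 to 10, 1 to 24, 2 to 24, 1 to 6, 8 to 31 and 0 to 3 for the same comparisons in that order, and 32 for DKO against INDY without WT KD 25, which is in neither group but in the same fit. It gave 120 to 1378 for the CSB and DKO average, 2 to 6 for the INDY and DKO average, 0 to 2, 0 to 17, 0 to 1, 0 to 0 and 0 to 2 for the diet on average and in WT, INDY, CSB and DKO, and 0 to 9, 0 to 0 and 0 to 617 for the diet response of INDY, CSB and DKO. The genotype level ran from -0.58 to -0.51 for Ercc6 and from -6.89 to -6.79 for Slc13a5, whose size depends on the pseudocount, and the microglia list median from 0.96 to 1.19.

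Values that changed sign were not called. Ercc6 did so in DKO against CSB on SD (0.12 with 1 surrogate variable, 0.04 with the covariates, 0.01 without the libraries with high forebrain levels, -0.05 to 0.05 over single libraries) and on KD (-0.02 without those libraries, -0.02 to 0.24 over single libraries). In INDY against WT on SD it read 0.02 with the surrogate variable and 0.02 with the covariates. Without the libraries with high forebrain levels it read -0.01 in the INDY and DKO average, 0.10 for the diet on average and 0.12 in CSB, and with the surrogate variable 0 for the diet in DKO. In the same setting Fat2, Gabra6 and Pcp2 read -0.15, -0.24 and -0.16 for the diet in DKO, and Slc13a5 read -0.22 in DKO against INDY on KD and 0 for the diet in DKO. Slc13a5 in DKO against INDY on SD read -0.03 with the surrogate variable and -0.03 with the covariates. Over single libraries left out, Ercc6 ran from -0.05 to 0.02 for the diet on average, -0.10 to 0.12 in CSB, -0.02 to 0.20 in DKO and -0.26 to 0 for the interaction on KD. Slc13a5 ran from -0.02 to 0.08 in the CSB and DKO average, -0.14 to 0.19 in DKO against INDY on KD, and 0 to 0.24 and 0 to 0.17 for the diet in DKO and INDY.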

Other observations

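The liver list and the levels below were chosen only after the values were seen, and no explanation was tested for them.

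Liver transcripts were spread unevenly over the libraries. Albumin (Alb) read 15.1 ± 8.60 (SD, n = 4) in WT SD, 1094 ± 2085 (n = 6) in INDY SD, 1410 ± 2448 (n = 6) in CSB SD and 497 ± 841 (n = 4) in DKO SD. On KD it read 74.0 ± 102 in WT, 1107 ± 1695 in INDY, 160 ± 200 in CSB and 359 ± 355 in DKO. The list's mean log2 level ranged from 1.24 to 8.35 in INDY KD and from 1.89 to 9.17 in CSB SD. A list of hindbrain genes outside the cerebellum ranged from 2.66 to 7.65 in INDY KD and from 2.89 to 6.86 in DKO SD.

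Copies near-identical to Gapdh traded places between libraries, also within groups. Gm12671 read 5358 ± 449 in WT SD and was listed at 0 in all 5 CSB KD libraries, where Gm7336 read 2189 ± 854. Gm7336 read 7.99 ± 16.0 in WT SD. In WT KD, Gm12671 was listed at 0 in libraries 7 and 25, where Gm7336 read 1422 and 2038, and read 6329 and 6174 in 12 and 28. In CSB SD it read 5464 and 4506 in 26 and 30 and was listed at 0 in the others, and in INDY KD it was listed at 0 in 46 alone. The sum of Gapdh and both copies differed by 0.40 (SE 0.072) between INDY and DKO and the rest, and Gapdh alone by 0.28. Further near-identical sequences, among them Gm3272, Gm3839, Gm10358, Gm10359 and Gm12033, were not in this sum, so it is not the total of the family.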
